A study of Mus musculus with 16 samples.

How the data were processed

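The 16 samples were mouse ileal epithelial cells collected by laser capture microdissection. Per the labels' protocols, the RNA was amplified in 2 rounds, labelled and hybridised to Affymetrix MG_U74Av2 oligonucleotide arrays, following the kits' and arrays' own protocols. Groups and replicate numbers were taken from the sample titles: WT (n = 6), adenoma (n = 5) and carcinoma (n = 5). The meaning of the prefix shared by the titles, the genotype and age of the mice, how regions were chosen for capture and the number of animals are not given in the sources used here.

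The deposited values were probe set intensities on a linear scale, 1 per array for 12488 probe sets, as the authors deposited them. The software that made them is not given in the sources used here. All values were above 0, and the mean of each array after trimming 2% at each end lay between 500.3 and 500.4, so the arrays were taken as already scaled to a common mean and were not normalized again. Median signal per array ran from 126.8 to 234.2. Scaling to a common mean leaves differences in the lower part of the distribution, and the 25th percentile was higher in WT than in the tumours.

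Values below the 25th percentile of all values (46.9, or 5.55 on the log2 scale) were set to that floor, and log2 was taken. A fold change of a gene near the floor is therefore understated, and a gene at the floor on every array of a group gives a bound. The 66 Affymetrix control probe sets were left out of tests. Gene symbols came from the platform annotation, with the Entrez identifiers of 10817 probe sets found in a mouse gene table of assembly GRCm38.p6, used for names only. A single symbol was given for 10833 probe sets, several for 396, and 1193 were not listed and stayed unnamed. Of several probe sets of a gene, the one with the highest mean was used. Genes above the floor on at least 5 of 16 arrays were tested.

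The 3 groups were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 13 residual degrees of freedom), which gives the groups a shared estimate of the spread, with Benjamini-Hochberg adjustment over the genes of each comparison at 0.05. All tests were two-sided. The 33 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. A further list test, fry, was run beside camera and is given below for some lists. Control measures were compared by exact permutation tests, adjusted over the 3 group pairs of a measure. The genes named were, per comparison, the 10 with the largest rise and the 10 with the largest fall past the threshold, without immunoglobulin or T cell receptor segments and unnamed clones, and per list up to 4 with the smallest p. For the genes changed in both tumours, the 5 with the largest smaller fold in each direction were named. The groups, tests, lists, naming rule and the first set of alternatives below were fixed before the data were examined. Genes at the floor in both groups were not named.

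The fit was tested on simulated data drawn from a normal distribution around each gene's mean with its fitted standard deviation, floored like the data, with 200 of 7455 genes changed. For adenoma against WT it recovered 1.5% of genes changed 1.5-fold, 22.4% of those changed 2-fold and 68.2% of those changed 4-fold, and 7.6% of its calls were false. For carcinoma against WT these were 3.0%, 14.9%, 65.2% and 3.5%. For carcinoma against adenoma it recovered 0% of genes changed 1.5-fold, 9.0% of those changed 2-fold and 68.2% of those changed 4-fold, and 3.8% of its calls were false. The simulation of unchanged tumour groups instead reassigned the residuals of the arrays.

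The first set of alternatives was quantile normalization, alignment of array medians, floors at the 10th and 40th percentile, no filter and a filter at 2 times the floor, the mean of a gene's probe sets, the replicate number as a block, array weights, a variance trend with robust estimation, a fit of only the 2 groups compared, the Gapdh 3' to 5' ratio as a covariate, and each array left out in turn. Added after seeing the data were the spike-in signal as a covariate and fits without the 4 WT arrays whose spike-in signal lay above every tumour array, with and without adenoma 4. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No 2 arrays held the same values. Probe sets with no single gene name were tested separately.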

Results

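Epithelial cells of the mouse ileum, the last part of the small intestine, were cut out of tissue sections by laser capture, and their RNA was amplified and hybridised to oligonucleotide arrays. The 16 arrays fell into 3 groups by their labels: 6 labelled WT, 5 labelled adenoma (a benign tumour) and 5 labelled carcinoma (an invasive tumour). The series is titled as a profile of the transition of the epithelium. The comparisons therefore asked how adenoma and carcinoma cells differed from WT cells, and how carcinoma differed from adenoma. The labels do not tie arrays to animals. If captures of the same group shared an animal, the p-values below are too small, because they then measure the spread between captured samples. Animals shared between the groups compared could instead make them too large. The number of arrays limits the precision. Of 8251 genes with a probe set of their own, 7455 were bright enough to test. All log2 fold changes are given ± their standard error.

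Control measures differed between WT and both tumour groups. The mean log2 signal of transcripts spiked into every hybridisation was 13.74 ± 1.0 (SD, n = 6) in WT, 12.24 ± 0.82 (SD, n = 5) in adenoma and 12.23 ± 0.50 (SD, n = 5) in carcinoma. It was lower in adenoma than in WT (two-sided exact permutation p = 0.0325, adjusted over the 3 group pairs 0.0488) and in carcinoma than in WT (exact p = 0.0238, adjusted 0.0488). Arrays WT 1, WT 2, WT 4 and WT 5 lay above every tumour array, of which adenoma 4 was highest at 13.47. The log2 ratio of 3' to 5' signal of Gapdh, a glycolytic enzyme whose probe sets serve as an RNA quality control, was 4.52 ± 0.39 in WT, 5.82 ± 0.24 in adenoma and 5.70 ± 0.58 in carcinoma. It was higher in adenoma (exact p = 0.00216, adjusted 0.00648) and in carcinoma (exact p = 0.00433, adjusted 0.00649) than in WT. The 3' signal of Gapdh itself was higher by 1.51 on the log2 scale in adenoma and by 1.37 in carcinoma. Its 5' signal differed by 0.21 and 0.19, less than the spread between arrays (exact p = 0.517 and 0.662). The ratio for beta-actin differed in the other direction, by -0.38 in adenoma (exact p = 0.0216, adjusted 0.0648) and by -0.21 in carcinoma (exact p = 0.297, adjusted 0.446), and neither difference passed the correction. Between carcinoma and adenoma, differences in the spike-in signal (exact p = 0.984), the Gapdh ratio (exact p = 0.698) and the beta-actin ratio (exact p = 0.516) were within the spread between arrays.

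**Figure D1:**
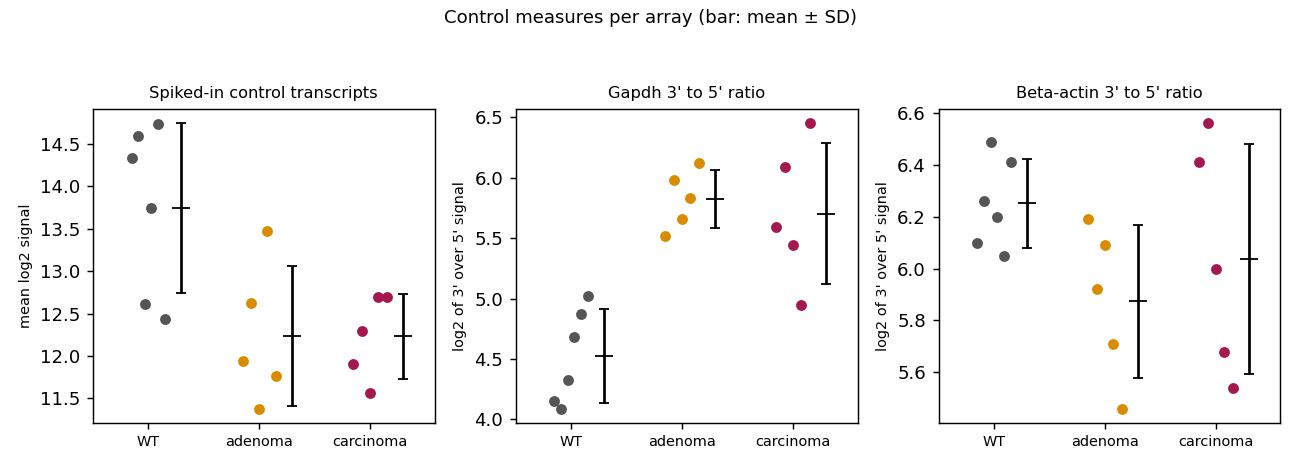
Control measures of each array (points) by group, with mean and SD as bars: the mean log2 signal of spiked-in transcripts, and the log2 ratio of 3' to 5' signal of Gapdh and of beta-actin. The spike-in signal averaged 13.74 in WT against 12.24 in adenoma and 12.23 in carcinoma, and the Gapdh ratio 4.52 against 5.82 and 5.70.

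In adenoma, the largest rise against WT was in clusterin (Clu), a secreted chaperone, which was 121-fold higher (log2 6.92 ± 0.42, adjusted p = 4.26e-09). Complement factor I (Cfi) was 80.0-fold higher (6.32 ± 0.43) and the protease cathepsin E (Ctse) 76.7-fold (6.26 ± 0.33). S100g, an intestinal calcium-binding protein, was 63.5-fold higher (5.99 ± 0.53), and the mast cell proteases Mcpt2 and Mcpt1 were 39.9-fold and 21.7-fold higher. Annexin A1 (Anxa1), the laminin chain Lamb3, the plasminogen activator Plat and Wfdc18 completed the 10 largest rises, at 34.7-fold, 25.5-fold, 24.8-fold and 24.2-fold. Among the largest falls, the fatty acid transporter Slc27a2 was 19.5-fold lower (-4.29 ± 0.33), the urea cycle enzyme Otc 11.1-fold (-3.47 ± 0.33) and the glucuronosyltransferase Ugt2b5 10.5-fold. The antimicrobial lectin Reg3a was 10.5-fold lower and the brush border peptidase Enpep 10.3-fold. Slc1a1, Tnxb, Adamdec1, Fbp1 and Psmb9 were 8.35-fold, 8.31-fold, 7.68-fold, 7.27-fold and 7.25-fold lower.

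In all, 617 of the 7455 genes (8.3%) changed in adenoma against WT at a limma adjusted p of 0.05, 300 higher and 317 lower, and 274 and 284 of these by at least 2-fold. These p-values are too small if arrays of the same group shared animals. The split depended on the scaling of the arrays. As deposited, 48.6% of the changed genes were higher and the median log2 fold change of all genes was -0.14. After quantile normalization these were 62.3% and -0.02, and with array medians aligned 75.9% and 0.12. The count fell to 181 without the 4 WT arrays of high spike-in signal, to 398 with the spike-in signal as a covariate, to 69 with the Gapdh ratio as a covariate and to 384 without adenoma 5. The Gapdh ratio of every adenoma array lay above that of every WT array, so this covariate nearly repeated the grouping. Among the genes named above, the Gapdh covariate ended 4 calls, with a wider standard error in each. Reg3a went from -3.39 ± 0.46 to -3.17 ± 0.81 (adjusted p = 0.0828) and Adamdec1 from -2.94 ± 0.57 to -3.09 ± 1.0 (0.227). Enpep went from -3.36 ± 0.62 to -2.61 ± 1.08 (0.408) and Tnxb from -3.05 ± 0.51 to -2.26 ± 0.88 (0.362). Tnxb was also lost without the 4 WT arrays (-2.77 ± 0.73, adjusted p = 0.0608), and Psmb9 when adenoma 4 was left out as well (from -2.86 ± 0.45 to -2.36 ± 0.59, adjusted p = 0.0544). Probe sets of one gene did not always move together: 1 of the 3 for Ctse, 1 of the 2 for Enpep and 1 of the 2 for Slc1a1 showed the difference at an unadjusted p of 0.05. With the mean of a gene's probe sets, Ctse was higher by 2.46 in place of 6.26, Enpep lower by -1.76 in place of -3.36 and Slc1a1 by -1.90 in place of -3.06, and Clu, at 5.50, was no longer above Cfi. These still passed.

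Genes of the fetal and regenerating intestine had the highest median of the 33 lists in adenoma, on arrays that also differed from WT in spike-in signal and Gapdh ratio. Of 16 tested, 9 rose and 0 fell (10 and 1 when adjusted over the list alone), with a median of 1.55. The list differed from the other genes by camera (adjusted p = 8.08e-12, and 0.00769 with an estimated correlation). Besides Clu and Anxa1, Anxa8 was higher by 3.78 ± 0.34 and Anxa3 by 3.73 ± 0.36. Matrix protease and invasion genes rose in 13 of 32 (16 adjusted over the list alone), with a median of 0.74 and camera adjusted p = 1.4e-11 (0.00769 with an estimated correlation). Beside Ctse, Lamb3 and Plat they included the integrin chain Itgav (1.94 ± 0.24). Of 22 Wnt/beta-catenin target genes, 6 rose and 1 fell (also 6 and 1 adjusted over the list alone), with camera adjusted p = 0.00102 (0.0374 with an estimated correlation). Those with the smallest p were the matrix protease Mmp7 (2.46 ± 0.39), the transcription factor Jun (2.34 ± 0.40), Id2 (1.95 ± 0.37) and the urokinase receptor Plaur (2.17 ± 0.45). Each also belongs to another list, Mmp7 and Plaur to that of matrix protease and invasion, so the list calls are not separate evidence. Among 12 stem cell genes, Prom1 (2.48 ± 0.34) and Tnfrsf19 rose and the water channel Aqp4 fell (-1.48 ± 0.44), also when adjusted over the list alone. Tnfrsf19 lay at the floor on all 6 WT arrays and was higher by at least 1.39 on the log2 scale. Their camera adjusted p was 0.016, and 0.0508 with an estimated correlation.

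Glycolysis and hypoxia genes rose in 5 of 23 (8 adjusted over the list alone), with camera adjusted p = 5.01e-05 (0.00845 with an estimated correlation), as did the 3' signal of Gapdh. They included the hypoxia-inducible factor Hif1a (2.98 ± 0.44), Ddit4 (1.65 ± 0.33), Pgam1 (1.30 ± 0.26) and Pkm (1.90 ± 0.41). Cholesterol synthesis genes rose in 4 of 23 (8 adjusted over the list alone), with camera adjusted p = 2.17e-05 (0.0508 with an estimated correlation). These were the fatty acid desaturase Fads1 and the sterol pathway enzymes Msmo1, Fdft1 and Fdps, higher by 0.92 to 1.84. Of 32 inflammation and prostaglandin genes, 5 rose and 2 fell (8 and 3 adjusted over the list alone), with camera adjusted p = 0.00516 (0.0508 with an estimated correlation). The acute phase gene Saa3 (4.21 ± 0.38), Il1rn (2.34 ± 0.31), lactoferrin (Ltf, 2.81 ± 0.40) and the chemokine Cxcl1 (2.93 ± 0.48) had the smallest p. Ribosome biogenesis genes passed camera (adjusted p = 0.0363, and 0.29 with an estimated correlation), with 3 of 28 higher (Nhp2, Pes1 and Fbl) and Polr1b lower.

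Several lists did not pass camera in adenoma although members changed. Immediate early and heat shock genes (median 0.03, adjusted p = 0.167) held 4 rises, in Jun, Gadd45b (1.80 ± 0.45), Atf3 (1.73 ± 0.43) and Fos (1.56 ± 0.41). TGF-beta and BMP genes (0.09, adjusted p = 0.0871) held 5, in Id2, Id1 (1.28 ± 0.29), Tgif1, Id3 and Smad7. Among interferon-induced genes (-0.39, adjusted p = 0.197), Ifitm3 rose (2.87 ± 0.36) and Irgm1 (-1.59 ± 0.33), Mx2 and Ifi204 fell. Among junction genes (-0.01, adjusted p = 0.197), the tight junction gene Cldn4 rose (2.60 ± 0.46). DNA replication genes (0.01, adjusted p = 0.604), mitosis genes (0.11, adjusted p = 0.0626) and cytosolic ribosomal proteins (0.03, adjusted p = 0.9) each held a single changed gene, Fen1 lower, Mad2l1 higher and Rps24 lower. Lipid absorption genes (-0.19, adjusted p = 0.481) held 3 falls, in Dgat1, Ppara and Fabp2, of -1.52 to -2.16.

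Genes of antigen presentation by MHC molecules fell in adenoma in 8 of 21 (14 adjusted over the list alone), with a median of -1.08 and camera adjusted p = 1.11e-06 (0.0374 with an estimated correlation). They included the immunoproteasome subunits Psmb9 (-2.86 ± 0.45) and Psmb8 (-1.89 ± 0.33), B2m, the light chain of class I molecules (-1.57 ± 0.29), and the peptide transporter Tap1 (-1.40 ± 0.26). Markers of T, B and plasma cells, which also carry MHC molecules, were lower on the same arrays (median -0.56, camera adjusted p = 0.00062, and 0.224 with an estimated correlation). Brush border and digestion genes fell in 7 of 19 (7 adjusted over the list alone), with a median of -1.01. Besides Enpep these included Dpp4 (-1.36 ± 0.25), Mep1a (-1.72 ± 0.33) and the fructose transporter Slc2a5 (-1.61 ± 0.37). Their camera adjusted p was 5.69e-05, and 0.0975 with an estimated correlation. Xenobiotic metabolism genes fell in 5 of 33 and rose in 1 (10 and 1 adjusted over the list alone), with camera adjusted p = 0.0047 (0.155 with an estimated correlation). Ugt2b5, Sult1d1 (-2.65 ± 0.29) and Ces1d (-2.68 ± 0.47) were lower and Gstm5 (1.55 ± 0.25) higher. Of 8 bile acid genes, 2 fell (5 adjusted over the list alone), the exporter subunit Slc51a (-2.03 ± 0.31) and the bile acid receptor Nr1h4 (-1.26 ± 0.32), with camera adjusted p = 0.00798 (0.0641 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.36 with 0 of 55 changed singly (camera adjusted p = 0.016, and 0.0508 with an estimated correlation).

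Markers of other cell types moved apart in adenoma. Enteroendocrine markers fell in 4 of 20 (6 adjusted over the list alone), with a median of -0.68 and camera adjusted p = 9.4e-05 (0.00769 with an estimated correlation). They were the secretory granule protein Chgb (-2.34 ± 0.40), the prohormone convertase Pcsk1 (-1.70 ± 0.27) and the hormones Gip and Ghrl. Goblet cell markers fell in 5 of 14 (5 adjusted over the list alone), among them Clca1 (-2.70 ± 0.34) and Fcgbp (-1.78 ± 0.30), with camera adjusted p = 0.016 (0.286 with an estimated correlation). T, B and plasma cell markers fell in 6 of 22 (6 adjusted over the list alone), among them the plasma cell gene Jchain (-1.79 ± 0.27) and Il2rb (-1.80 ± 0.30). Their camera adjusted p was 0.00062, and 0.224 with an estimated correlation. By fry, goblet (adjusted p = 0.00947) and T, B and plasma cell markers (0.00544) passed, and ribosome biogenesis genes (0.147) did not. Endothelial markers passed camera upward (adjusted p = 0.0363, and 0.123 with an estimated correlation) through Sox17 (3.22 ± 0.33), which is also a transcription factor of endoderm, and Cdh5 (2.17 ± 0.32). Paneth cell markers went both ways, with Pla2g2a (3.13 ± 0.47) and Mmp7 higher and Reg3a lower (adjusted p = 0.913). Smooth muscle markers did not pass (adjusted p = 0.0584), with Myh11 (-2.49 ± 0.44) and Acta2 (-1.68 ± 0.46) lower and Myl9 higher. Tuft cell markers did not pass (adjusted p = 0.975), although Avil rose (2.95 ± 0.52). Lists for macrophages and neutrophils (0.669), fibroblasts and matrix (0.39), neurons and glia (0.142), erythrocytes (0.975) and pancreatic acinar cells (0.481) did not pass either.

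Some list calls in adenoma were lost or gained in other settings, and like the counts they assume that arrays did not share animals. A lost call does not by itself show a smaller difference. With the Gapdh ratio as a covariate, the calls for Wnt targets (adjusted p = 0.164, median 0.03 in place of 0.31), stem cell genes (0.0791, 0.56 in place of 0.52), ribosome biogenesis (0.613, -0.07 in place of 0.27), brush border (0.164, -0.78 in place of -1.01) and xenobiotic metabolism (0.448, -0.26 in place of -0.61) were lost. Without the 4 WT arrays of high spike-in signal, those for stem cell genes (0.266, median 0.29), ribosome biogenesis (0.544, 0.10), goblet cells (0.124, -0.32 in place of -0.45) and T, B and plasma cells (0.266, -0.37 in place of -0.56) were lost. Oxidative phosphorylation was lost with array medians aligned (0.0775, with a median of -0.06) and without adenoma 4 (0.0709, with a median of -0.30 in place of -0.36). The stem cell call was also lost with medians aligned (0.0582), where the median was larger at 0.65, with the floor at the 40th percentile (0.0881, median 0.26) and with the spike-in signal as a covariate (0.277, median 0.25). That covariate also ended the calls for ribosome biogenesis (0.266, median 0.13), goblet cells (0.214, -0.24) and T, B and plasma cells (0.266, -0.19). Goblet cells were lost without WT 5 (0.0709, median -0.26), and endothelium without WT 6 (0.102), adenoma 3 (0.0538) or adenoma 4 (0.0709). The endothelial call also failed with medians aligned (0.0516), the floor at the 10th or 40th percentile (0.084 and 0.128), no filter (0.119), a stricter filter (0.0626) and only the 2 groups fitted (0.0523), and over all these fits its median ran from 0 to 0.36 against 0.11. Ribosome biogenesis was lost without any 1 of WT 1, WT 2, WT 4, adenoma 2, adenoma 3, adenoma 4, adenoma 5 and carcinoma 1 (adjusted p from 0.0512 to 0.085). It also failed after quantile normalization (0.0809), with the floor at the 40th percentile (0.0747), a stricter filter (0.0829), array weights (0.0808) and only the 2 groups fitted (0.0523). Its median was 0.19 to 0.29 with single arrays left out and 0.23 to 0.27 in the latter settings, against 0.27.

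Other lists passed in adenoma only under alternatives. Smooth muscle markers, with a median of -0.56, passed downward in 13 of 31, among them quantile normalization (adjusted p = 0.0366), aligned medians (0.0455) and the fits without the 4 WT arrays of high spike-in signal (median -0.83, adjusted p = 0.00647) and without adenoma 4 as well (-0.92, 0.00501). They also passed without any 1 of WT 1, WT 3, WT 4, WT 5, adenoma 4 and carcinoma 3 (0.0313 to 0.049). Mitosis genes passed upward in 7, among them aligned medians (median 0.41, 0.0269) and the fits without WT 3 (0.0289), WT 6 (0.031) or adenoma 4 (0.0371). TGF-beta and BMP genes passed upward after quantile normalization (0.0412) and with the Gapdh ratio as a covariate (0.0244), and neurons and glia downward with array weights (0.0483).

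Calls for several single list members in adenoma were lost when 1 of the 16 arrays was left out. This held for 14 of the arrays for Myl9, 13 for Fdps, 12 for Rps24, 11 for Fen1, 10 each for Aqp4, Ifi204, Ghrl and Fdft1, and 8 each for Fabp2 and Mx2. It held for 7 each for Fbl, Acta2, Msmo1 and Id3, and for 6 for Fads1. Fos was lost without WT 2, adenoma 1, adenoma 2 or adenoma 3 (adjusted p from 0.05 to 0.0639) and Tnfrsf19 without adenoma 2, adenoma 3 or adenoma 5 (0.0626 to 0.0799). Polr1b was lost without adenoma 1 or adenoma 5 (0.0545 and 0.0566), Tgif1 without adenoma 2 or adenoma 5 (0.0574 and 0.0542) and Atf3 without adenoma 1 or adenoma 2 (0.0526 and 0.0501). With the mean of probe sets, the calls for Itgav (0.62, adjusted p = 0.0584), Atf3 (0.42, 0.399), Fos (0.39, 0.48), Gadd45b (1.16, 0.0551), Gstm5 (1.0, 0.0799), Fdps (0.89, 0.0959) and Ifi204 (-0.65, 0.105) were lost. Over all alternatives, Rps24, Ifi204 and Myl9 passed in 9 of 31, Fdps in 11, Aqp4 in 12, Fabp2 and Fdft1 in 14 and Tnfrsf19 in 23, and Fen1 passed in 9 and Ghrl in 10 of 30. The value was -0.13 for Rps24 with the spike-in signal and 0 for Fabp2 with the Gapdh ratio as a covariate, and 0.34 for Tnfrsf19 with the floor at the 40th percentile.

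**Figure D2:**
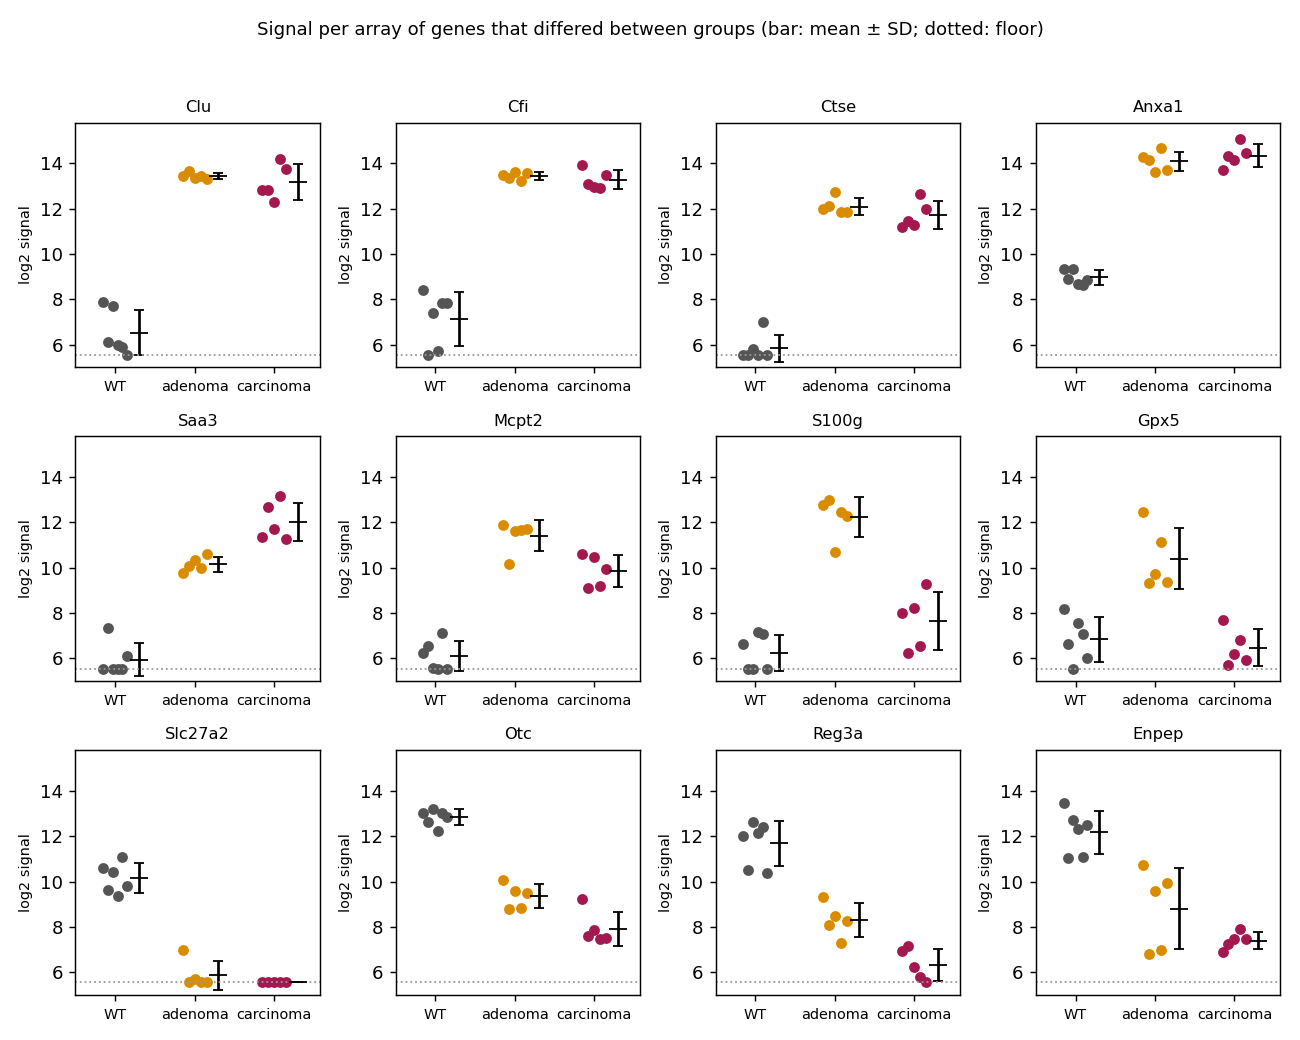
Log2 signal of 12 genes on each array (points) by group, with mean and SD as bars and the floor of 5.55 as a dotted line. Clu averaged 6.92 log2 units higher in adenoma and 6.66 higher in carcinoma than in WT, S100g differed by -4.58 between carcinoma and adenoma, and Slc27a2 lay at the floor on every carcinoma array.

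In carcinoma, Clu was again the gene with the largest rise against WT, at 101-fold (6.66 ± 0.42, adjusted p = 6.25e-09), followed by Cfi (71.1-fold), Saa3 (68.3-fold, 6.09 ± 0.38) and Ctse (58.9-fold). Anxa1 was 41.3-fold higher, Wfdc18 was higher by 5.32 ± 0.46 on the log2 scale, and Lamb3 was 25.2-fold, Plat 21.6-fold, the folate-processing enzyme Ggh 20.3-fold and Mcpt1 15.6-fold higher. The largest falls were in Reg3a, 41.1-fold lower (-5.36 ± 0.46), Otc, 30.1-fold lower (-4.91 ± 0.33), and Enpep, 27.5-fold lower (-4.78 ± 0.62). Slc27a2 lay at the floor on all 5 carcinoma arrays and was at least 24.2-fold lower. The amine oxidase Maoa was 18.9-fold lower, Ocm 16.9-fold, Usp2 15.1-fold, Ccl25, a chemokine of the small intestine, 14.3-fold, Clca1 13.5-fold and the lipoprotein component Apoa1 11.6-fold lower.

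In all, 675 genes (9.1%) changed in carcinoma against WT at a limma adjusted p of 0.05, 310 higher and 365 lower, and 270 and 335 of these by at least 2-fold. As in adenoma, animals shared within a group would make these p-values too small. As deposited, 45.9% of the changed genes were higher, against 58.7% after quantile normalization and 73.7% with array medians aligned. The median log2 fold change of all genes was -0.14, -0.01 and 0.15 in these scalings. The count was 209 without the 4 WT arrays of high spike-in signal, 382 with the spike-in signal as a covariate and 100 with the Gapdh ratio as a covariate. In that ratio every carcinoma array but carcinoma 4 lay above every WT array, so the covariate nearly repeated the grouping. The Gapdh covariate ended the calls for Enpep (from -4.78 ± 0.62 to -4.09 ± 1.01, adjusted p = 0.0546) and Apoa1 (from -3.54 ± 0.69 to -1.42 ± 0.96, adjusted p = 0.609). Apoa1 was also lost without the 4 WT arrays (-2.79 ± 0.98, adjusted p = 0.178). The standard error was wider in each of these fits. The difference was seen in 1 of the 3 probe sets for Ctse, 1 of the 2 for Enpep and 2 of the 3 for Maoa. With the mean of probe sets, Ctse was higher by 2.15 in place of 5.88, Enpep lower by -2.52 in place of -4.78, Maoa by -1.81 in place of -4.24, and Clu, at 5.30, was no longer above Cfi and Saa3. These still passed.

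Matrix protease and invasion genes rose in carcinoma in 16 of 32 (17 higher and 1 lower adjusted over the list alone), with a median of 1.01 and camera adjusted p = 2.55e-12 (0.00873 with an estimated correlation). Fetal and regeneration genes rose in 8 of 16 (10 and 1 adjusted over the list alone), with a median of 1.34 and adjusted p = 9.54e-11 (0.0098 with an estimated correlation). The carcinoma arrays, too, differed from WT in spike-in signal and Gapdh ratio. Itgav was higher by 1.72 ± 0.24, Anxa8 by 3.96 ± 0.34 and Anxa3 by 3.93 ± 0.36. Wnt/beta-catenin targets rose in 6 of 22 (8 higher and 1 lower adjusted over the list alone), with camera adjusted p = 0.000218 (0.0188 with an estimated correlation). They included Mmp7 (2.73 ± 0.39), Id2 (1.88 ± 0.37), Jun (1.95 ± 0.40) and Plaur (1.79 ± 0.45). Stem cell genes rose in 3 of 12 (6 adjusted over the list alone), with adjusted p = 0.000857 (0.0166 with an estimated correlation). These were Prom1 (3.21 ± 0.34), Tnfrsf19, higher by at least 1.39 than the floor at which all WT arrays lay, and Cdca7 (1.15 ± 0.35). Inflammation genes rose in 8 of 32 and fell in 2 (10 and 4 adjusted over the list alone), with adjusted p = 0.000214 (0.0188 with an estimated correlation). Besides Saa3, Il1rn (2.30 ± 0.31), Cxcl1 (3.52 ± 0.48) and Ltf (2.49 ± 0.40) rose.

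Glycolysis and hypoxia genes rose in carcinoma in 6 of 23 (6 adjusted over the list alone), with adjusted p = 0.00404 (0.0324 with an estimated correlation). Hif1a (3.06 ± 0.44), Pkm (1.81 ± 0.41), Ddit4 (1.42 ± 0.33) and the glucose transporter Slc2a1 (1.65 ± 0.46) had the smallest p. Cholesterol synthesis genes rose in 4 of 23 (8 adjusted over the list alone), including Fads1 (0.99 ± 0.25) and Fdps (1.89 ± 0.55), with adjusted p = 0.000162 (0.0684 with an estimated correlation). Mitosis genes rose in 3 of 34, Mad2l1 (1.32 ± 0.29), Prc1 and Kif4 (adjusted p = 0.00404, and 0.102 with an estimated correlation). Ribosome biogenesis genes rose in 3 of 28 and fell in 1 (4 and 1 adjusted over the list alone), with adjusted p = 0.022 (0.249 with an estimated correlation). Immediate early genes rose in 3 of 32, Jun, Fos and Dusp1 (adjusted p = 0.0484, and 0.186 with an estimated correlation). DNA replication (adjusted p = 0.056, with Pcna higher by 1.11 ± 0.26), ribosomal proteins (0.516), junctions (0.125, with Cldn4 higher by 2.07 ± 0.46) and interferon-induced genes (0.206, with Ifitm3 higher by 2.48 ± 0.36) did not pass. TGF-beta and BMP genes did not pass either (0.4), with 4 higher, among them Id2 and Inhba (1.67 ± 0.42), and Tgfb2 lower.

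Brush border and digestion genes fell in carcinoma in 10 of 19 (15 adjusted over the list alone), with a median of -1.82 and camera adjusted p = 6.11e-10 (0.0188 with an estimated correlation). After Enpep, those with the smallest p were Mep1a (-2.30 ± 0.33), the amino acid transporter subunit Slc3a1 (-2.74 ± 0.40) and Dpp4 (-1.54 ± 0.25). Xenobiotic metabolism genes fell in 14 of 33 and rose in 1 (19 and 3 adjusted over the list alone), with adjusted p = 5.63e-06 (0.031 with an estimated correlation). Ugt2b5 (-2.87 ± 0.31), Sult1d1 (-2.67 ± 0.29), Adh1 (-2.81 ± 0.45) and Cyp2d26 (-2.86 ± 0.53) were among those that fell. MHC presentation genes fell in 10 of 21 (10 adjusted over the list alone), with adjusted p = 4.34e-06 (0.031 with an estimated correlation). They included B2m (-1.85 ± 0.29), Psmb8 (-2.05 ± 0.33), Psmb9 (-2.72 ± 0.45) and the class II chain H2-Ab1 (-2.60 ± 0.45). Markers of T, B and plasma cells were lower here too (median -0.59, adjusted p = 0.00168, and 0.24 with an estimated correlation). Bile acid genes fell in 3 of 8 (5 adjusted over the list alone), Slc51a (-3.05 ± 0.31), Abcc2 (-1.97 ± 0.38) and Nr1h4 (-1.17 ± 0.32), with adjusted p = 0.00112 (0.031 with an estimated correlation). Lipid absorption genes fell in 6 of 23 and rose in 1 (6 and 1 adjusted over the list alone), with adjusted p = 0.00168 (0.156 with an estimated correlation). Ppara (-1.83 ± 0.29), Dgat1 (-2.09 ± 0.36), the fatty acid-binding protein Fabp2 (-3.43 ± 0.63) and Apoa1 were among the falls. Oxidative phosphorylation genes had a median of -0.30, with Ndufb9, Uqcrc2 and Ndufa1 lower (3 of 55, and 0 adjusted over the list alone), and adjusted p = 0.0118 (0.0312 with an estimated correlation).

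Among cell type markers in carcinoma, enteroendocrine genes fell in 5 of 20 (5 adjusted over the list alone), with camera adjusted p = 0.000162 (0.0098 with an estimated correlation). They included Pcsk1 (-1.63 ± 0.27), Chgb (-2.06 ± 0.40), Chga (-1.87 ± 0.44) and Gip (-1.73 ± 0.44). T, B and plasma cell markers fell in 4 of 22 (4 adjusted over the list alone), among them Jchain (-1.96 ± 0.27) and Prf1 (-1.35 ± 0.33), with adjusted p = 0.00168 (0.24 with an estimated correlation). Goblet markers fell in 5 of 14 and rose in 1 (also 5 and 1 adjusted over the list alone), with adjusted p = 0.0426 (0.358 with an estimated correlation). Clca1, Muc3 (-2.31 ± 0.32), Fcgbp (-1.89 ± 0.30) and Zg16 (-3.18 ± 0.53) fell, and Retnlb, at the floor on all WT arrays, rose by at least 2.52. Smooth muscle markers fell in 2 of 11 (6 lower and 1 higher adjusted over the list alone), Myh11 (-2.79 ± 0.44) and Acta2 (-1.94 ± 0.46), with adjusted p = 0.021 (0.156 with an estimated correlation). Of the fibroblast and matrix genes, 4 of 33 rose, including Col1a1 (1.41 ± 0.23) and Col5a2 (1.75 ± 0.35), and 2 fell (adjusted p = 0.171). Avil rose in the tuft cell list (2.67 ± 0.52), which did not pass (adjusted p = 0.935). The lists for Paneth cells (0.854), macrophages and neutrophils (0.297), endothelium (0.108), neurons and glia (0.192), erythrocytes (0.766) and acinar cells (0.194) did not pass.

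Of the list calls in carcinoma, which also assume separate animals, those for ribosome biogenesis (adjusted p = 0.371, median 0.08 in place of 0.15), lipid absorption (0.318, -0.37 in place of -0.72), glycolysis (0.0602, 0.05 in place of 0.31) and immediate early genes (0.202, 0.03 in place of 0.10) were lost with the Gapdh ratio as a covariate. Without the 4 WT arrays of high spike-in signal, mitosis (0.447, median 0.05 in place of 0.17), ribosome biogenesis (0.313, 0.21), goblet cells (0.171, 0.06 in place of -0.43), T, B and plasma cells (0.412, -0.16 in place of -0.59) and immediate early genes (0.267, 0.05) were lost. With the spike-in signal as a covariate, mitosis (0.641, median 0.05), ribosome biogenesis (0.164, 0.22), goblet cells (0.278, 0.02), T, B and plasma cells (0.409, -0.10), immediate early genes (0.554, 0.11) and smooth muscle (0.0867, -0.42 in place of -0.72) were lost. Smooth muscle was also lost without WT 6 (0.0528, median -0.68). Oxidative phosphorylation had a median of 0.03 and was lost with array medians aligned (0.0703). Goblet cells were lost without WT 4 (0.0641), WT 5 (0.133) or carcinoma 5 (0.155), with array weights (0.201) and with only the 2 groups fitted (0.0578), at medians of -0.30 to -0.43. Ribosome biogenesis was lost without carcinoma 2 (0.0537, median 0.15) and after quantile normalization (0.0505, median 0.25). Immediate early genes were lost without any 1 of WT 1, WT 3, WT 5, adenoma 1, adenoma 2, adenoma 4, carcinoma 2, carcinoma 3 and carcinoma 5 (adjusted p from 0.051 to 0.15). They were also lost after quantile normalization (0.101), with the floor at the 40th percentile (0.126), a stricter filter (0.0682), the mean of probe sets (0.083), a variance trend (0.0526) and only the 2 groups fitted (0.0578). Their median was 0.10 to 0.18 with single arrays left out and 0.10 to 0.24 in these settings, against 0.10.

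Settings that ended calls in carcinoma also added some. Endothelial markers, with a median of 0.09, passed upward with the Gapdh ratio as a covariate (median 0.13, adjusted p = 0.0335), with the spike-in signal as a covariate (0.64, 0.0343), without the 4 WT arrays of high spike-in signal (0.61, 0.0275) and without adenoma 4 as well (0.61, 0.0249). Fibroblast and matrix genes, with a median of 0.10, passed upward in the latter 3 fits (medians 0.21, 0.16 and 0.16, adjusted p = 0.0113, 0.0322 and 0.0318). Macrophage and neutrophil markers passed with the Gapdh covariate (median 0.17, 0.0235). DNA replication genes passed in 8 of 31 settings, among them quantile normalization (0.24, 0.0392), aligned medians (0.39, 0.034) and the fits without WT 1 (0.0361), WT 2 (0.0367), WT 6 (0.0172), adenoma 3 (0.041) or carcinoma 1 (0.0284).

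Calls for single list members in carcinoma were likewise lost when 1 of the 16 arrays was left out. This held for 10 of the arrays for Cdca7, 8 each for Prc1, Kif4 and Ndufa1, and 6 each for Fdps and Ndufb9. Uqcrc2 was lost without WT 1, WT 2, carcinoma 1 or carcinoma 5 (adjusted p from 0.0635 to 0.086), Slc2a1 without WT 1, carcinoma 4 or carcinoma 5 (0.0513 to 0.0911) and Nr1h4 without WT 4, carcinoma 4 or carcinoma 5 (0.053 to 0.0632). Tnfrsf19 was lost without carcinoma 1 or carcinoma 5 (0.0622 and 0.061), Tgfb2 also without carcinoma 1 or carcinoma 5 (0.0584 and 0.058), Dusp1 without carcinoma 4 or carcinoma 5 (0.0677 and 0.0516) and Inhba without carcinoma 1 (0.0559). With the mean of probe sets, the calls for Col1a1 (0.16, adjusted p = 0.783), Fos (0.65, 0.218), Fdps (0.98, 0.061) and Ndufa1 (-0.59, 0.1) were lost, and Itgav was higher by 0.68 (0.0335). Over all alternatives, Cdca7 and Ndufa1 passed in 13 of 31 and Tnfrsf19 in 23, with a value of 0.40 for Tnfrsf19 with the floor at the 40th percentile.

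**Figure D3:**
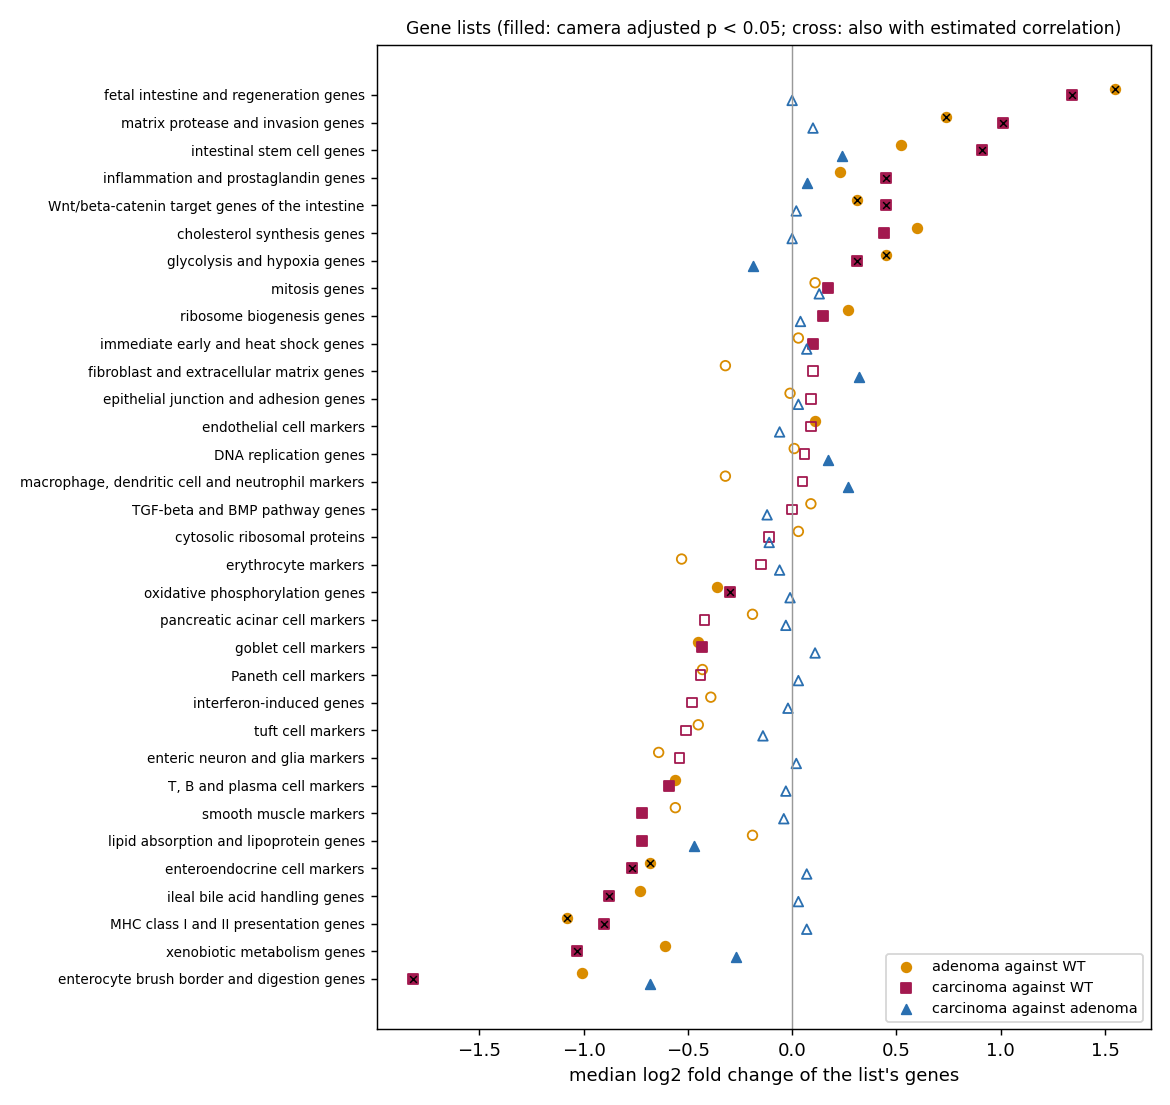
Median log2 fold change of the genes of each of 33 lists (x axis) for adenoma against WT (circles), carcinoma against WT (squares) and carcinoma against adenoma (triangles). Filled symbols mark lists past a camera adjusted p of 0.05 and crosses those that also pass with an estimated correlation; the median of brush border genes was -1.01 in adenoma and -1.82 in carcinoma against WT.

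Of the 617 genes changed in adenoma and the 675 changed in carcinoma against WT, 436 were the same genes changed in the same direction, 220 higher and 216 lower, and 0 changed in opposite directions. The rises with the largest smaller fold were those of Clu, Cfi, Ctse, Anxa1 and Lamb3, and the falls those of Slc27a2, Otc, Reg3a, Enpep and Slc1a1. A further 181 genes passed in adenoma alone and 239 in carcinoma alone, which does not show that they differed between the tumours. Independent lists of these sizes would share 12.5 higher and 15.5 lower genes. In 100 simulations of unchanged groups, in which the residuals of all 16 arrays were reassigned, a median of 0 genes were shared. Reassigning removes any offset common to the WT arrays, so the simulation does not test whether such an offset made shared calls. With the WT arrays split so that each tumour group had its own 3, the median over 20 splits was 127 shared genes (range 107 to 151), of a median of 301.5 genes called in adenoma and 319.5 in carcinoma. Across genes, which are not independent replicates, the fold changes correlated with r = 0.887, against 0.483 in the simulation and a median of 0.641 with split WT arrays. Their covariance was 0.502 against a simulated 0.074, a difference of 0.429. The count was 139 without the 4 WT arrays of high spike-in signal, 284 with the spike-in signal as a covariate and 59 with the Gapdh ratio as a covariate. It too rests on p-values that assume separate animals.

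**Figure D4:**
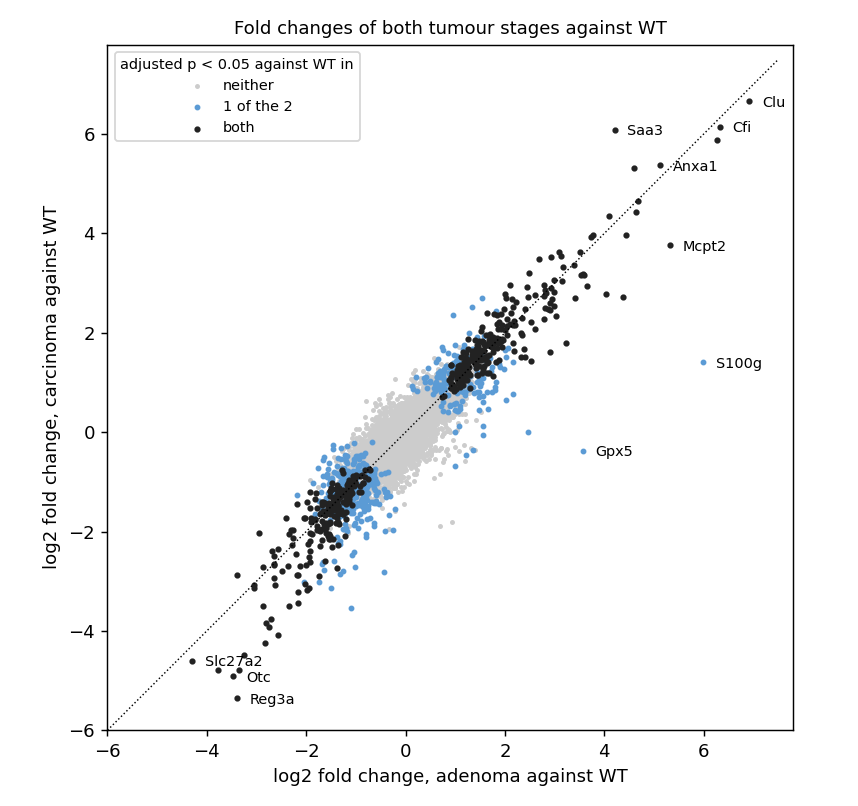
Log2 fold change of each tested gene in adenoma (x axis) and in carcinoma (y axis) against WT, with the line of equal change dotted. Black points are the 436 genes past an adjusted p of 0.05 in both, blue points those past it in 1 of the 2 and grey points the others; S100g and Gpx5 lie below the line.

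In carcinoma against adenoma, S100g was 23.9-fold lower (-4.58 ± 0.56, adjusted p = 0.000956), and each of the 5 adenoma arrays lay above each of the 5 carcinoma arrays. Gpx5, a secreted glutathione peroxidase, was 15.3-fold lower (-3.93 ± 0.59, adjusted p = 0.00992). Against WT, S100g was higher by 1.41 ± 0.53 in carcinoma and did not pass as deposited (adjusted p = 0.107), although it passed after quantile normalization and with array medians aligned. Gpx5 was higher by 3.57 ± 0.57 in adenoma than in WT. These were the 2 of the 7455 genes that changed between the tumours at a limma adjusted p of 0.05, and 185 had an unadjusted p under 0.05. Here, too, animals shared within a group would make the p-values too small, and animals shared between adenoma and carcinoma could make them too large. Neither gene passed when only the arrays of these 2 groups were fitted (adjusted p = 0.0543 for S100g and 0.0546 for Gpx5) or with the floor at the 10th percentile (0.0558 and 0.126). The differences stayed at -4.58 and -3.93, with standard errors of 0.60 and 0.61 in the former fit and 0.72 and 0.70 in the latter. Gpx5 also failed without adenoma 4 (0.0527), carcinoma 2 (0.0551) or carcinoma 5 (0.05), without the filter (0.0941), and without both adenoma 4 and the 4 WT arrays of high spike-in signal (0.0629). The count of 2 became 18 with array weights, 6 without the 4 WT arrays of high spike-in signal, 5 with the floor at the 40th percentile or without WT 2, and 1 without the filter, without adenoma 4, carcinoma 2 or carcinoma 5, or without both adenoma 4 and the 4 WT arrays. It was 0 with the floor at the 10th percentile and with only the 2 groups fitted. In simulated data with 200 genes changed, the fit for this comparison recovered 68.2% of genes changed 4-fold and 9.0% of those changed 2-fold. The adjusted threshold is easier to pass when many genes change. With a count of 2 it was stricter here, so these shares do not show how many such differences were missed.

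As groups, brush border genes were lower in carcinoma than in adenoma (median -0.68, 0 of 19 singly, camera adjusted p = 7.81e-08, and 0.12 with an estimated correlation). So were lipid absorption genes (median -0.47, 0 of 23 singly, 2 adjusted over the list alone, adjusted p = 2.39e-07, and 0.12 with an estimated correlation). Xenobiotic metabolism genes had a median of -0.27, with 0 of 33 changed singly and 1 adjusted over the list alone (adjusted p = 0.000257, and 0.135 with an estimated correlation). Single members had values of -1.35 ± 0.42 for Slc3a1, -2.45 ± 0.72 for Apoa1 and -2.38 ± 0.47 for Adh1, none past the threshold over all genes (adjusted p = 1, 0.913 and 0.124). Fibroblast and matrix genes were higher (median 0.32, 0 of 33 singly or adjusted over the list alone, adjusted p = 2.85e-07, and 0.127 with an estimated correlation). Values were 0.80 ± 0.24 for Col1a1 and 1.12 ± 0.32 for Fbln2, neither past the threshold. Also higher were macrophage and neutrophil markers (median 0.27, adjusted p = 0.00493, and 0.171 with an estimated correlation) and DNA replication genes (0.17, adjusted p = 0.00878, and 0.193 with an estimated correlation). Stem cell genes (0.24, adjusted p = 0.0325, and 0.127 with an estimated correlation) and inflammation genes (0.07, adjusted p = 0.0199, and 0.135 with an estimated correlation) were higher too. In the inflammation list Saa3 had the smallest p (1.89 ± 0.40, adjusted p = 0.2, past the threshold over the list alone). Glycolysis and hypoxia genes were lower (-0.19, adjusted p = 0.0325, and 0.135 with an estimated correlation).

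None of these list calls between the tumours held with an estimated correlation, and they share the limit on animals. These lists did not pass fry either (adjusted p from 0.291 to 0.363). By exact permutation tests of the list mean per array, chosen after the data were seen, none of the 33 lists passed after adjustment over the lists. The smallest exact p that 5 and 5 arrays allow, 0.00794, became 0.262, so the adjustment left little room for any list to pass. The adjusted p was 0.262 for brush border (exact p = 0.0159) and stem cell genes (exact p = 0.00794), and 0.299 for lipid absorption (exact p = 0.0317), xenobiotic metabolism (exact p = 0.0635) and fibroblast genes (exact p = 0.0476). At the preset correlation, the camera calls for brush border, lipid absorption and fibroblast genes passed with each array left out. Without adenoma 1, xenobiotic (adjusted p = 0.0756, median -0.21), DNA replication (0.0993, 0.15), stem cell (0.0756, 0.15) and glycolysis genes (0.133, -0.12) were lost. Macrophage markers were lost without adenoma 2 (0.0846, median 0.26) or carcinoma 4 (0.088, median 0.14), and so were inflammation genes (0.111 and 0.145, medians 0.03 and -0.01). Stem cell genes were also lost without adenoma 2 (0.0857), adenoma 4 (0.106), carcinoma 1 (0.08), carcinoma 3 (0.0577), carcinoma 4 (0.0519) or carcinoma 5 (0.0516), at medians of 0.20 to 0.32, around the 0.24 with all arrays. Glycolysis genes were also lost without adenoma 2 (0.0857), adenoma 5 (0.152), carcinoma 3 (0.155), carcinoma 4 (0.0861) or carcinoma 5 (0.0504), at medians of -0.15 to -0.19. Stem cell genes failed as well with medians aligned (0.0651, median 0.26) and array weights (0.079, median 0.22), and inflammation genes with the floor at the 10th percentile (0.0896) and no filter (0.0543). Glycolysis genes failed with medians aligned (0.0559), the floor at the 10th or 40th percentile (0.0896 and 0.108) and a stricter filter (0.0844), at medians of -0.16 to -0.18. Mitosis genes (median 0.13, adjusted p = 0.0744) passed in 5 of 31 settings, among them the fits without adenoma 3 (0.0359), adenoma 5 (0.0265) or carcinoma 5 (0.0219). Bile acid genes (0.03, 0.126) passed downward in 3, one of them without WT 4 (-0.03, 0.0331), and endothelial markers (-0.06, 0.179) downward with the mean of probe sets (0.0201). The other lists, among them Wnt targets (median 0.02, adjusted p = 0.749), MHC presentation (0.07, 0.899), matrix protease and invasion (0.10, 0.773) and fetal and regeneration genes (0.00, 0.891), did not pass.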

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

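Of the tests in this part, the splits of the arrays were chosen before the result was seen. Those of gut segment and of the fibroblast list for differences between carcinoma and adenoma were chosen after it. So were those of the dim and bright genes called lower. The tests of single arrays for S100g and of all dim genes had their limits set before they were run. They concern a gene and arrays that were picked from these data.

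Splits of the arrays into other groups of the same sizes were drawn, 100 per comparison with the real one included and each array taken as a separate animal. To the 1 in 100 that this number of splits can resolve, they made chance unlikely for the counts against WT. The real grouping gave 617 genes for adenoma against WT and was the only 1 of 100 to reach that number, with 230 the highest of the others. For carcinoma against WT it gave 675, also reached by 1 of 100 splits, with 218 the highest other. For the genes changed in both against WT it gave 436 (1 of 100, highest other 1). For carcinoma against adenoma it gave 2 (1 of 100 splits, highest other 1). A margin of 1 gene does not exclude chance there, and the count was 0 with only these 2 groups fitted and with the floor at the 10th percentile. A split that followed the spike-in signal gave 25 genes within WT and adenoma and 0 within WT and carcinoma. It mixed WT and tumour arrays in each of its groups, which widens the spread, so these low counts do not measure the part of the spike-in signal.

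Dim genes lay lower in the tumours than in WT: over the 2982 dimmest genes, the median difference of the tumour arrays from WT was -0.34 on the log2 scale. Less labelled target on the 4 WT arrays of high spike-in signal could raise dim signals there. Against WT 3 and WT 6 alone, whose spike-in signal lay within the range of the tumours, the shift of all dim genes shrank to -0.09 (-0.13 and 0.02 against each), which goes with that explanation. For called falls, genes were selected in 1 tumour group against the 4 other WT arrays and measured as the other tumour group against WT 3 and WT 6: among the 2982 brightest genes, the 61 selected in adenoma and the 82 selected in carcinoma were lower by medians of -1.33 and -1.21 (-1.06 or lower against either array), which argues against less target as the whole cause there. The 131 and 177 dim genes selected were lower by -0.63 and -0.55, against -0.07 and -0.06 for the dim genes not selected. Against WT 6 alone the 177 were lower by -0.48, which missed by a small margin a limit set after the data were seen. For dim genes, the parts of less target and of the tumour state, itself untested, cannot be told apart.

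S100g was lower in carcinoma than in adenoma by -4.58 and Gpx5 by -3.93, which were the 2 differences between the tumours past the threshold. A single array or probe set does not account for S100g: the highest adjusted p without 1 adenoma or carcinoma array was 0.00612, and the second S100g probe set differed by -3.91 (exact permutation p = 0.00794). S100g is made mainly in the upper small intestine, so captures of adenoma from further up could raise it. The 16 proximal genes tested were lower in carcinoma by -1.19 ± 0.47 (SE, exact p = 0.0397), but the 11 ileal genes were lower too (-0.37 ± 0.11, exact p = 0.0159), which goes against a shift of segment alone, and the gap between the lists missed the threshold (-0.82 ± 0.49, exact p = 0.151); without brush border genes these were -1.35 ± 0.49 (12 genes, exact p = 0.0317), -0.24 ± 0.13 (9 genes, exact p = 0.103) and -1.11 ± 0.56 (exact p = 0.0794). Because 13 of the 16 proximal and 10 of the 11 ileal genes tested also belong to the lists above, several of which were lower in carcinoma, segment and enterocyte differentiation cannot be told apart here.

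Fibroblast and matrix genes were higher in carcinoma than in adenoma, by 0.36 ± 0.15 (SE) for the list mean per array. The mean was 8.28 ± 0.25 (SD) in carcinoma, 7.92 ± 0.23 in adenoma and 8.19 ± 0.25 in WT. Carcinoma thus lay near WT, and adenoma lay below WT by -0.28 (exact permutation p = 0.0887). The mean of 5 other stromal lists was also below WT in adenoma (-0.33, exact p = 0.0303). The difference between the tumours therefore does not show a gain of the list mean over WT in carcinoma. More stroma of every kind in the carcinoma captures would raise other stromal lists alike, but the mean of the macrophage, endothelial, smooth muscle, lymphocyte and neuron lists differed by 0.02 ± 0.14, and the gap between it and the fibroblast list was larger in carcinoma (0.34 ± 0.08, exact p = 0.0159). That gap was 0.75 ± 0.12 (SD) in carcinoma, 0.42 ± 0.14 in adenoma and 0.36 ± 0.24 in WT, and carcinoma was not tested against WT for it. The macrophage list alone was higher by 0.26 in carcinoma than in adenoma (exact p = 0.0873, adjusted over the lists 0.32), so more fibroblasts and macrophages together stay open. For the list itself, chance assignment of the arrays was not excluded: its exact p was 0.0476, and 0.299 when adjusted over the 33 lists. The smallest exact p that 5 and 5 arrays allow, 0.00794, became 0.262 after this adjustment, so the adjusted test could hardly decide the question. More fibroblasts alone and matrix genes made by the tumour cells were not tested against each other.

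Single arrays stood apart from their group for 5 of 73 sets of values examined, about the share of 1 in 20 that chance gives. On the log2 scale, Mcpt2 was 10.18 in adenoma 2 where the nearest other array was 11.64, and Otc was 9.24 in carcinoma 1 (nearest 7.84). Ocm was 6.43 in adenoma 4 (nearest 7.70). Usp2 was 9.54 in WT 6 (nearest 10.31) and 5.80 in adenoma 5 (nearest 7.70).

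Probe sets without a single gene name were not part of the counts above. Of 1248 tested, 100 changed in adenoma against WT (30 higher, 70 lower), 139 in carcinoma against WT (38 higher, 101 lower) and 0 in carcinoma against adenoma.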

How the results depend on the processing

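The fits with the spike-in signal or without WT arrays of high spike-in signal were chosen after seeing the data. With the Gapdh ratio as a covariate, 69 genes changed in adenoma against WT, 100 in carcinoma against WT and 59 in both. With the spike-in signal as a covariate these were 398, 382 and 284. Without the 4 WT arrays of high spike-in signal they were 181, 209 and 139, with 6 in carcinoma against adenoma. Without adenoma 4 as well they were 171, 243 and 136, with 1. Fewer arrays were fitted there. The Gapdh ratio ran from 4.09 to 5.02 in WT and from 5.52 to 6.12 in adenoma. Of the carcinoma arrays, only carcinoma 4 (4.95) lay in the WT range. As a covariate this ratio nearly repeated the groups, which widens standard errors. Its lower counts neither show nor exclude that RNA quality made the calls. For the spike-in covariate the cause was not tested. For carcinoma against adenoma, the count of 2 became 0 with the floor at the 10th percentile, 5 with it at the 40th, 1 without the filter, 0 with only these 2 groups fitted and 18 with array weights; the cause was not tested. Leaving out each array in turn gave 384 (without adenoma 5) to 674 genes in adenoma against WT, 494 to 773 in carcinoma against WT, 1 (without adenoma 4, carcinoma 2 or carcinoma 5) to 5 (without WT 2) in carcinoma against adenoma, and 312 to 497 in both. The other settings kept each count within 1.5 times. Of the calls, 474 of 617 were shared after quantile normalization and 446 with array medians aligned. Beta-actin in place of Gapdh turned the 3' to 5' ratio, to -0.38 in adenoma and -0.21 in carcinoma against WT; the cause was not tested.

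Nothing in the labels says that the numbers in the titles pair the samples. After each gene's group mean was subtracted, correlations of same-numbered arrays of different groups ran from -0.265 to 0.398, which cannot rule pairing out. The fit with a replicate block left out WT 6 and gave 726, 841, 2 and 531 genes. Without WT 6 and with no block these were 674, 773, 2 and 497. The fit with the block ended the list calls for endothelium in adenoma (adjusted p = 0.139) and for goblet cells (0.0862) and smooth muscle (0.0797) in carcinoma. It added mitosis in adenoma (0.0341) and DNA replication in carcinoma (0.0152). Except for goblet cells, the fit without WT 6 alone made the same changes. No named gene changed direction under the alternatives run. Of the calls for named genes, 137 were lost with the Gapdh ratio as a covariate, 68 with the spike-in signal as a covariate, 92 without the 4 WT arrays and 89 without adenoma 4 as well, against 3 to 32 in the other settings that lost any. Genes near the floor of 46.9 were limited by signal over background: their folds are understated, and a fall to the floor gives a bound.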

Other observations

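The genes and families in this part were chosen after the main results were seen. Of 9 annexins tested, calcium-dependent membrane-binding proteins, 6 were higher in adenoma and 5 in carcinoma than in WT, and 0 were lower. No family in this part was tested as a set. Beyond Anxa1, Anxa3 and Anxa8, Anxa2 was higher by 1.73 ± 0.33 in adenoma and by 1.72 in carcinoma and Anxa5 by 1.70 ± 0.30 and 1.98, while Anxa10 passed in adenoma (1.88 ± 0.52, adjusted p = 0.031) and not in carcinoma (1.38, adjusted p = 0.106). The annexin counts were the same after quantile normalization and with array medians aligned. Of 9 laminin chains, Lamb3, Lama3 (2.98 ± 0.45 in adenoma, 2.82 in carcinoma) and Lama5 (2.79 ± 0.30 and 2.96) were higher, and Lama2 was lower (-1.57 ± 0.33 and -1.51), under each of the 3 scalings, and Lamb2 also passed in adenoma under quantile normalization and with medians aligned. The claudins Cldn4 and Cldn6 went opposite ways, Cldn4 higher by 2.60 ± 0.46 in adenoma and Cldn6 lower by -1.68 ± 0.32, under each scaling. Of the other families looked at, as deposited, 3 of 11 cathepsins and 2 of 13 S100 genes were higher in each tumour, and 2 of 28 keratins were higher in adenoma, while in carcinoma 1 was higher and 2 lower. Which keratins, S100 genes and, in carcinoma, cathepsins passed changed with the scaling, and with array medians aligned 2 keratins were higher and 0 lower in carcinoma.

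Of 9 mast cell genes tested, 3 were higher in both tumours as deposited: Mcpt1, Mcpt2 and Cpa3. Mcpt2 was higher by 5.32 ± 0.39 in adenoma and by 3.76 in carcinoma, Mcpt1 by 4.44 ± 0.45 and 3.96, and Cpa3 by 2.90 ± 0.40 and 1.61. The mast cell tryptase Tpsb2 (-0.54 in adenoma, adjusted p = 0.344), the receptor chains Fcer1a (0.96, adjusted p = 0.164) and Ms4a2 (-0.82, adjusted p = 0.202) and Kit (0.48, adjusted p = 0.473) did not pass. The chymase Cma1 did not pass in adenoma as deposited (1.21, adjusted p = 0.0932) but did under quantile normalization and with array medians aligned, where 4 of 9 were higher.

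Control probe sets for the B1 and B2 repeats, short interspersed elements of the mouse genome, were dimmer on average in the tumours, but not against every WT array. The log2 signal of B2 was 16.97 ± 0.60 (SD, n = 6) in WT, 15.90 ± 0.49 (n = 5) in adenoma (exact permutation p = 0.0173, adjusted 0.026) and 15.89 ± 0.28 (n = 5) in carcinoma (exact p = 0.013, adjusted 0.026). For B1 the differences were -0.82 in adenoma (exact p = 0.0303, adjusted 0.0455) and -1.13 in carcinoma (exact p = 0.00433, adjusted 0.013). The B2 signal of WT 3 and WT 6, 73158 and 79886, lay within the tumours' range of 41822 to 99258, while the 4 WT arrays of high spike-in signal lay between 142958 and 195037. The B1 signal of WT 3 and WT 6, 41720 and 37539, lay within the tumours' range of 14196 to 55069, and so did that of WT 5, 55003, an array of high spike-in signal.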
